A study of Mus musculus with 18 samples.

How the data were processed

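RNA sequencing was done on 18 samples of mouse acute myeloid leukemia (AML), 3 in each of 6 groups. Per the labels' protocols, MLL/ENL Nras leukemia cells that were wild type for p53 (p53WT) or lacked it (p53null) were transplanted into syngeneic C57BL/6 mice, and mice with established disease received CX-5461, an inhibitor of RNA polymerase I (Pol I), or vehicle for 10 or 72 h before sacrifice. GFP-positive tumour cells were sorted from the bone marrow, and libraries were made with a TruSeq RNA kit that does not mark strand. Samples of p53null AML were taken at 10 h only, and those of p53WT AML at 10 h and 72 h.

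The authors deposited 3 tables, 1 per genotype and time. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie, HTSeq and edgeR were used with the mm9 build. The notes give no order or settings, and the gene annotation is not given in the sources used here. Per the file headers, each table holds the authors' log2 fold change, log2 mean CPM (counts scaled to the library total), p-value and false discovery rate (FDR) from edgeR. The table for p53WT AML at 10 h also holds deposited raw counts per gene for 6 libraries, and the other 2 tables hold no counts. The count columns name the arm (untreated or treated) and a number from 1 to 3, while the sample titles of this comparison carry the numbers 3 to 5, so that the columns are not tied to titles. Each column was therefore assigned to its group and not to a titled sample. The tables hold 12679 genes (p53WT, 10 h), 12861 genes (p53null, 10 h) and 12838 genes (p53WT, 72 h). Genes with low counts were absent from them, and all 12679 genes of the count table exceeded 1 CPM in at least 3 libraries. Ensembl IDs were paired with symbols through a gene name table for 12237, 12366 and 12362 of these IDs. No coordinates are given, because the reference at hand was of another build than mm9.

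The sign of the authors' log2 fold change was checked on the count table. Its Pearson correlation across genes with the log2 ratio of mean CPM, CX-5461 over vehicle, was 1.00, so that positive values mean higher with CX-5461. The same orientation was taken for the other 2 tables, where it could not be checked on counts.

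The counts of p53WT AML at 10 h were normalized by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with treatment as the only term and 4 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are CX-5461 over vehicle, log2 CPM values were made with a prior count of 2, and CPM values per group are means with the SD over 3 libraries. For the other 2 tables, the planned fits could not be run without counts. Genes past an FDR of 0.05 and their log2 fold changes were therefore taken from the authors' deposited tables, with no SD, SE or value per library. For the same reason the planned fits of the genotype and time interactions and the contrast of the 2 vehicle groups at 10 h were not run.

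A total of 24 gene lists were fixed before the data were examined, 18 for pathways, leukemia genes and cell maturation and 6 for other marrow cell types. The first 18 were p53 targets, Pol I machinery, ribosome biogenesis, ribosomal proteins, G1/S genes, G2/M genes, replication-dependent histones, MLL fusion and stemness genes, primary granule genes, neutrophil maturation genes, monocyte and macrophage genes, BCL2 family and caspases, DNA damage checkpoint and repair, interferon-stimulated genes, NF-kB targets, integrated stress response, cholesterol synthesis and immediate early genes. The other 6 were erythroid genes, B cell genes, T and NK cell genes, megakaryocyte genes, stromal and endothelial genes, and mast cell, basophil and eosinophil genes. Lists were tested on the counts with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. In the authors' deposited tables lists were tested with cameraPR on the signed normal score of the authors' p-value, at the same preset correlation. Without values per library, no correlation could be estimated there. Benjamini-Hochberg adjustment was over the lists of a comparison. These set tests compare genes and not animals.

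The genes named were fixed by rule before the data were examined. The rule took the 8 largest rises and the 8 largest falls past the threshold at a mean of at least 5 CPM (with every CX-5461 library on 1 side of every vehicle library where counts existed, and without genes known only by a model name), then 3 members of each list with the smallest p, then Trp53, Cdkn1a, Mdm2, Bbc3, Myc, Hoxa9, Meis1 and Kit. Members named beyond these were chosen after their values were seen. Overlaps of calls were tested with Fisher's exact test, two-sided. The tests of list differences between comparisons, with cameraPR on the ranked difference of the authors' log2 fold changes, were chosen after the data were seen.

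The alternatives planned before the data were examined were RLE size factors, library size alone, DESeq2 1.42.0, the edgeR exact test, limma-voom, the authors' own columns, other filters, an absolute log2 fold change of at least 1, a block for the replicate number in the titles, which could not be run, and leaving out each library. Those added afterwards were an FDR of 0.01, robust estimation, the number in the count column names as a block, the mean log2 CPM of the erythroid list as a covariate and rank forms of the list tests. The erythroid level differed between the arms at 10 h, so that this covariate was confounded with treatment. Calls lost with it therefore do not show that a list followed the erythroid genes. The fits were tested on simulated counts for the 12679 genes of p53WT AML at 10 h. Of 50 genes each at an absolute log2 fold change of 0.5, 1, 2 and 4, the edgeR quasi-likelihood test recovered 44%, 88%, 100% and 100%, with 0 in the wrong direction and 17 of 12479 unchanged genes called. Camera and cameraPR each recovered the list that was shifted and called 0 of 23 others. Genes were simulated independently, in random lists and with the same dispersion in both arms. The check therefore does not cover lists of correlated genes or arms of unlike spread.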

Results

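RNA was sequenced from GFP-positive MLL/ENL Nras AML cells sorted from mouse bone marrow after CX-5461 or vehicle. The 18 samples formed 6 groups of 3: p53WT AML at 10 h, p53null AML at 10 h and p53WT AML at 72 h, each with a CX-5461 and a vehicle group. Counts were available for the 6 libraries of p53WT AML at 10 h, with 48118513, 27921504 and 22090394 counts over the retained genes in vehicle libraries 1, 2 and 3. The CX libraries 1, 2 and 3 had 37244725, 21578685 and 23150282. The 10 most abundant genes took 4.32% to 5.24% of the counts of a library. Log2 CPM correlated across genes at r = 0.974 to 0.987 between vehicle libraries and at 0.995 to 0.996 between CX libraries. The vehicle libraries thus differed more among themselves. The depth behind the other 2 tables is unknown. The labels name no batch and do not say how many animals gave the samples. Sample titles of p53WT and p53null AML at 10 h carry different tags, and those at 72 h carry neither. What the tags stand for is not given, so that different leukemias behind the groups cannot be excluded. The p-values of single genes below measure the spread between these samples. Those of camera, cameraPR and Fisher's exact test compare genes and do not measure that spread.

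Trp53, the gene that encodes p53, was measured at 168, 142 and 160 CPM in the 3 vehicle libraries and at 183, 182 and 180 CPM in the 3 CX libraries of p53WT AML at 10 h. Its mean was 61.5 CPM in the authors' deposited table for p53null AML, 169 CPM in that for p53WT AML at 10 h and 163 CPM in that for p53WT AML at 72 h. Which part of Trp53 the p53null cells lack is not stated, and the authors' deposited tables were normalized separately. Its log2 fold change with CX-5461 was 0.21 (SE 0.0668) in p53WT AML at 10 h, with an adjusted p of 0.0826 in the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment. The authors' deposited tables gave a Trp53 log2 fold change of 0.01 (FDR 1) in p53null AML and -0.10 (FDR 0.332) in p53WT AML at 72 h.

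The first comparison asked how p53WT AML responded to 10 h of CX-5461. The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067) rose 4.77-fold, from 51.8 ± 3.33 CPM in vehicle to 247 ± 15.0 CPM with CX-5461 (mean ± SD, n = 3), a log2 fold change of 2.25 (SE 0.0706). Phlda3 (ENSMUSG00000041801), which encodes an inhibitor of AKT, rose 14.4-fold, from 2.24 ± 0.359 to 32.8 ± 2.15 CPM, and the kinase gene Plk2 rose from 0.786 ± 0.403 to 10.6 ± 2.05 CPM. The pro-apoptotic genes Bbc3 (PUMA) and Bax rose from 8.83 ± 0.889 to 28.3 ± 1.34 CPM and from 88.3 ± 4.55 to 174 ± 5.55 CPM. Mdm2, which encodes the ubiquitin ligase of p53, rose from 90.9 ± 9.17 to 147 ± 5.51 CPM. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 8.19e-05 for Cdkn1a and Phlda3, 0.005 for Plk2, 0.000506 for Bbc3 and Bax, and 0.0134 for Mdm2.

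Of 33 measured genes in the list of p53 targets, 22 rose and 0 fell with adjustment over all genes, and 26 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 0.82, and the list rose by camera (adjusted p = 3.22e-17), with an adjusted p = 0.427 with an estimated correlation and 0.00109 by fry. Further members that rose were Zmat3 (1.69), Sesn2 (1.76), a stress-induced regulator of mTORC1, and cyclin G1, Ccng1, which went from 173 ± 8.22 to 394 ± 13.5 CPM. Gadd45a (log2 fold change -1.19) and Btg2 (-0.55) did not pass the test, with adjusted p of 0.103 and 0.188 by the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment. Without any single CX library, 13 members were still called higher and 0 lower. Relative to the CX mean, the list's median log2 CPM was -0.79, -0.79 and -0.92 in vehicle libraries 1, 2 and 3. Outside the list, rises at a mean of at least 5 CPM included those of the ephrin receptor gene Epha2 (2.14), the p53-induced noncoding RNA Trp53cor1 (1.91) and the thiamine transporter gene Slc19a2 (1.83, from 18.4 ± 1.28 to 65.7 ± 5.60 CPM).

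**Figure D1:**
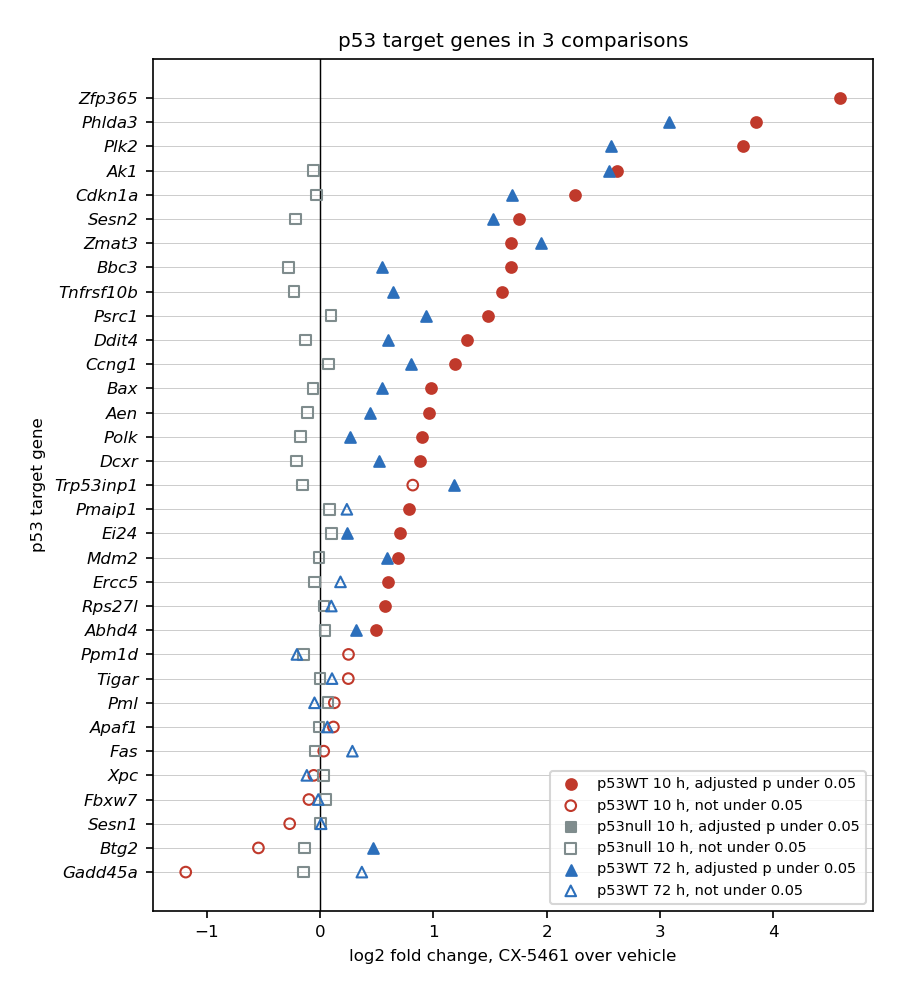
Log2 fold change of each p53 target gene (vertical axis) with CX-5461 over vehicle (horizontal axis) in p53WT AML at 10 h (circles, from counts), p53null AML at 10 h (squares) and p53WT AML at 72 h (triangles), the last 2 from the authors' deposited tables, with filled symbols for genes with an adjusted p under 0.05. Of the measured genes, 22 of 33 were higher in p53WT AML at 10 h, 20 of 32 at 72 h in the authors' deposited table, and 0 of 29 in p53null AML in the authors' deposited table.

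Genes that build ribosomes were higher in p53WT AML after 10 h of CX-5461. Of 40 measured ribosome biogenesis genes, all 40 had a positive log2 fold change, 25 rose over all genes tested and 37 rose when adjusted over the list alone, with a median log2 fold change of 0.39. Examples were the ribosome assembly factor genes Rrs1 (0.48, SE 0.0609, from 101 ± 5.70 to 140 ± 6.65 CPM), Pno1 (0.39) and Gnl3 (0.58), which encodes nucleostemin. This list rose by camera (adjusted p = 1.16e-16), with an adjusted p = 0.54 with an estimated correlation and 0.0326 by fry. Of 15 measured genes of the Pol I machinery, 4 rose, 0 fell, and 8 rose when adjusted over the list alone. The initiation factor gene Rrn3 had a log2 fold change of 0.33, the subunit gene Polr1b 0.54 and the selectivity factor gene Taf1c 0.42. The Pol I list rose by camera (adjusted p = 0.0026), with an adjusted p = 0.54 with an estimated correlation. Of 77 ribosomal protein genes, 0 passed the edgeR quasi-likelihood test (8 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom and 0 by the edgeR exact test). It was 0 when adjusted over the list alone too, and the median log2 fold change was 0.07. That list still rose by camera (adjusted p = 0.00101), with an adjusted p = 0.683 with an estimated correlation, and its camera adjusted p was 0.261 without vehicle library 3.

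Genes of cholesterol synthesis rose as well, 8 of 19 measured with 0 lower (14 and 0 when adjusted over the list alone), with a median log2 fold change of 0.36. Cyp51 (0.47) and Idi1 (0.47), both enzymes of the pathway, were among them. Camera gave the list an adjusted p = 1.68e-05, with an adjusted p = 0.54 with an estimated correlation. Without CX library 1, 2 or 3 the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes of the cholesterol, ribosome biogenesis and Pol I lists, against 8, 25 and 4 with all libraries. The list medians without CX library 1, 2 or 3 were 0.33, 0.35 and 0.39 for cholesterol synthesis and 0.37, 0.35 and 0.41 for ribosome biogenesis. For the Pol I machinery they were 0.14, 0.17 and 0.17, and each camera adjusted p of these 3 lists was 0.00502 or lower. Erythroid genes moved the other way in the same libraries, with a median log2 fold change of -4.96. With the mean log2 CPM of the erythroid list as a covariate, the medians were 0.20 for cholesterol synthesis and 0.28 for ribosome biogenesis, each with 0 genes called. Of these, 3 of 19 and 1 of 40 values were negative.

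Among apoptosis genes, 4 of 18 measured BCL2 family and caspase genes rose and 1 fell (4 and 3 when adjusted over the list alone). Besides Bbc3 and Bax, the pro-apoptotic Pmaip1 (NOXA, log2 fold change 0.79) and the anti-apoptotic Bcl2 (0.42) rose, and the pro-apoptotic Bmf fell by 0.83. The list's median log2 fold change was -0.04 and its mean 0.10, and camera did not call it (adjusted p = 0.631), while fry gave an adjusted p of 0.0326. Bbc3, Bax and Pmaip1 are also in the list of p53 targets and Bcl2 in that of MLL fusion and stemness genes. The result of the BCL2 family list is therefore not independent of those lists. Without CX library 1, 2 or 3, 2 members were called, both higher. Genes of DNA damage checkpoints and repair had 1 of 28 higher, the checkpoint kinase gene Atr (0.38), 0 lower, and 0 when adjusted over the list alone. Their median was 0.09 and the camera adjusted p = 0.0327, with an adjusted p = 0.54 with an estimated correlation. The camera adjusted p for this list was 0.0816 without vehicle library 2, 0.0851 without CX library 1 and 0.0569 without CX library 2, and Atr was not called without CX library 1, 2 or 3, by limma-voom or with library size alone. Other settings called more genes of the list: 3 higher without vehicle library 1, 3 higher and 1 lower without vehicle library 3, and 2 higher and 1 lower by DESeq2. With the erythroid level as a covariate the DNA damage median was -0.01, with 15 of 28 negative and 0 called by the edgeR quasi-likelihood test.

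Few cell cycle genes passed the test at 10 h in p53WT AML. Of 29 measured G2/M genes, 1 fell, the mitotic kinesin gene Kif23 (-0.42, from 100.1 ± 4.14 to 74.8 ± 4.81 CPM), and 0 rose, with 1 and 0 when adjusted over the list alone. DESeq2 called 7 lower, limma-voom and the exact test 1 each, and 10 were lower at an unadjusted p under 0.05. The median was -0.13 and 28 of 29 values were negative, with a camera adjusted p = 0.000584 and an adjusted p = 0.546 with an estimated correlation. Without CX library 1, 2 or 3 no G2/M gene was called by the edgeR quasi-likelihood test. Erythroid genes moved in the same direction (median -4.96), and with their level as a covariate the G2/M median was -0.03, with 18 of 29 negative and 0 called. Of 28 G1/S genes, 0 passed the edgeR quasi-likelihood test, also when adjusted over the list alone (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 0 by the edgeR exact test), and the camera adjusted p was 0.777 at a median of 0.00. Of 3 measured replication-dependent histone genes, 0 passed the edgeR quasi-likelihood test (2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 1 by the edgeR exact test, and 1 lower when adjusted over the list alone), with a median of -0.89 and a camera adjusted p of 0.0791. Without vehicle library 3 that camera adjusted p was 0.00316, with 2 of the histone genes lower, and with the erythroid covariate the histone median was 0.22, the opposite sign.

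Most genes of the MLL fusion program did not pass the test. Of 21 measured MLL fusion and stemness genes, 1 rose (Bcl2), 0 fell, and 0 passed when adjusted over the list alone, at a median log2 fold change of 0.12, a mean of -0.01 and a camera adjusted p of 0.0791. Log2 fold changes were 0.02 (SE 0.0502) for Hoxa9, 0.19 (SE 0.0854) for its cofactor Meis1, 0.32 (SE 0.113) for Myc and 0.24 (SE 0.113) for the stem cell factor receptor gene Kit, with edgeR quasi-likelihood adjusted p of 0.848, 0.177, 0.107 and 0.201 after Benjamini-Hochberg adjustment. The camera adjusted p of this list was 0.0257 without vehicle library 1, and Bcl2 was not called without CX library 1, 2 or 3 or by limma-voom. By contrast, DESeq2 called 5 genes of the list higher and 1 lower, the exact test 4 and 1, and the fit without vehicle library 3 called 3 and 1. With the erythroid covariate the list median was -0.01. Among 10 primary granule genes, 1 fell, the ficolin gene Fcnb (-1.58), and 0 rose (1 and 2 when adjusted over the list alone), at a median of 0.17, a mean of 0.03 and a camera adjusted p of 0.0671. Without vehicle library 1 this camera adjusted p was 0.023, with 3 primary granule genes higher, and 0 were called without any single CX library, by limma-voom or with robust quasi-likelihood estimation.

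Genes of mature neutrophils fell at 10 h, 16 of 24 measured with 0 higher (23 and 0 when adjusted over the list alone), at a median log2 fold change of -1.85. The calprotectin gene S100a9 went from 4249 ± 2263 to 1112 ± 251 CPM, the granule protein gene Ngp fell by 2.22, the protease gene Mmp25 by 1.95 and the receptor gene for G-CSF, Csf3r, by 0.42 (from 300.2 ± 7.35 to 224 ± 8.53 CPM). The list fell by camera (adjusted p = 5.82e-11), with an adjusted p = 0.54 with an estimated correlation and 0.0536 by fry. The number of lower neutrophil genes was 23 by DESeq2, 22 by the edgeR exact test, 10 by limma-voom and 4 with robust quasi-likelihood estimation. Of 22 monocyte and macrophage genes, 3 fell and 0 rose (10 and 0 when adjusted over the list alone), among them the chemokine receptor gene Ccr2 (-0.74), the oxidase gene Cybb (-1.30) and the complement gene C1qa (-2.79). Their median was -0.57, with a camera adjusted p = 6.59e-05 and an adjusted p = 0.54 with an estimated correlation. Of them, 11 were lower by DESeq2, 10 by the exact test and 2 by limma-voom. Leaving out vehicle library 1, 2 or 3 gave 8, 5 and 6 lower monocyte genes and 16, 15 and 20 lower neutrophil genes, and leaving out CX library 1, 2 or 3 gave 0 for both lists. Without CX library 1, 2 or 3 the neutrophil medians were -1.79, -1.91 and -1.77 and the monocyte medians -0.38, -0.47 and -0.72.

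Erythroid genes fell beside the neutrophil and monocyte genes. Of 12 measured, 7 fell and 0 rose (12 and 0 when adjusted over the list alone), at a median log2 fold change of -4.96, a camera adjusted p = 5.79e-06 and an adjusted p = 0.54 with an estimated correlation. DESeq2 and the edgeR exact test called all 12 lower. By contrast, limma-voom and robust quasi-likelihood estimation called 0, with 12 at an unadjusted p under 0.05 in the edgeR quasi-likelihood test. The band 3 gene Slc4a1 had 227, 755 and 27.2 CPM in vehicle libraries 1, 2 and 3 and 3.99 ± 1.69 CPM with CX-5461, and the globin gene Hbb-bs 1606, 5935 and 169 CPM against 71.4, 135 and 104 CPM in the CX libraries. Hbb-bs shares sequence with Hbb-bt, so its count is uncertain, and its edgeR quasi-likelihood adjusted p was 0.0521 after Benjamini-Hochberg adjustment. Among genes with a mean of at least 5 CPM, large falls past the test included those of the red cell genes Aqp1 (-7.34), Slc4a1 (-6.40), Trim10 (-6.30), Kel (-6.26), Rhag (-6.21) and Add2 (-6.08), and of the immunoglobulin gene Ighg2c (-6.21, from 53.2 ± 33.9 to 0.675 ± 0.304 CPM). Relative to the CX mean, the erythroid median was 4.09, 5.88 and 1.15 log2 units higher in vehicle libraries 1, 2 and 3, and the neutrophil median 1.60, 2.42 and 0.76 higher. The monocyte and macrophage median was 0.18, 0.79 and 0.59 higher, another order of the vehicle libraries. Without vehicle library 3, 12 erythroid genes were lower, and without CX library 1, 2 or 3, 0 were. The erythroid medians without CX library 1, 2 or 3 were -4.83, -5.18 and -4.97.

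The other marrow cell lists were not called by camera. The 3 measured B cell genes had 0 calls by the edgeR quasi-likelihood test (1 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom, 2 by the exact test) at a median of -1.86 (camera adjusted p 0.195). Of 4 T and NK cell genes, 1 rose, Nkg7 (0.51, from 64.3 ± 7.79 to 91.7 ± 0.559 CPM), a cytotoxic granule gene, while the median was -1.85 (camera adjusted p 0.696). The medians were -0.72 for 4 megakaryocyte genes (camera adjusted p 0.148), -0.42 for 4 stromal and endothelial genes (0.234) and -0.44 for 4 mast cell, basophil and eosinophil genes (0.0992). Each of these 3 lists had 0 calls by the edgeR quasi-likelihood test, 1 gene at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 1 by the exact test. Adjusted over the list alone, 1 B cell gene, 1 gene of the mast cell list and 2 T and NK cell genes were lower, Nkg7 was higher, and 0 of the megakaryocyte and stromal genes passed. Without vehicle library 3 the camera adjusted p was 0.0133 for the B cell and the mast cell list, and Nkg7 was not called without CX library 1, 2 or 3. With the erythroid covariate the medians of these 5 lists were above 0, at 1.76, 1.43, 0.35, 0.08 and 0.09 in the order given.

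**Figure D2:**
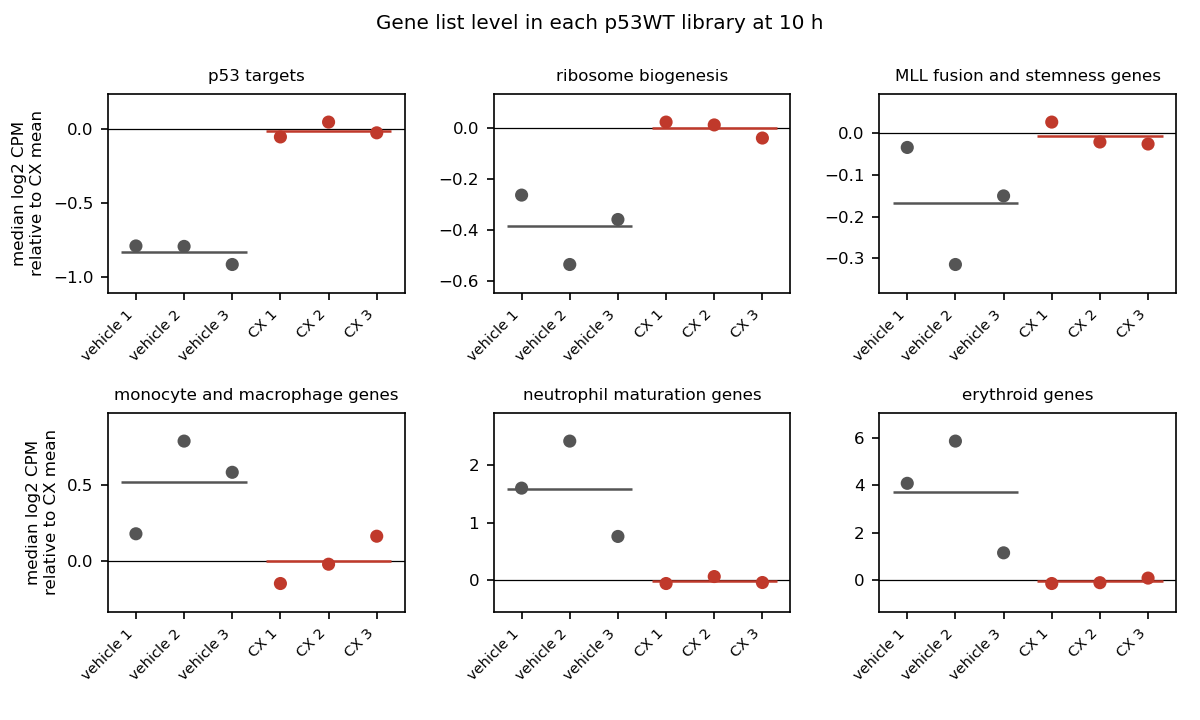
Median log2 CPM of 6 gene lists relative to the CX mean (vertical axis) in each of the 6 p53WT libraries at 10 h (horizontal axis), with a point per library and a line at each group mean. The p53 targets stood at -0.79, -0.79 and -0.92 in the vehicle libraries, and the erythroid genes at 4.09, 5.88 and 1.15.

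In the stress and signalling lists of p53WT AML at 10 h, few genes passed the test. Of 14 immediate early genes, 3 fell and 0 rose (5 lower and 1 higher when adjusted over the list alone), the transcription factor gene Klf6 by 0.94, the mRNA decay factor gene Zfp36 by 0.84 and the phosphatase gene Dusp1 by 1.65, at a list median of -0.56. The list fell by camera (adjusted p = 0.0073), with an adjusted p = 0.54 with an estimated correlation. Of 17 NF-kB targets, 1 rose, the adhesion gene Icam1 (0.50), and 1 fell, Nfkb1 (-0.21), with 1 and 6 when adjusted over the list alone, at a median of -0.30 (camera adjusted p = 0.00224, and adjusted p = 0.54 with an estimated correlation). DESeq2, the exact test and limma-voom called 6, 3 and 1 NF-kB targets lower, with 1 higher each. The same tools called 6, 6 and 1 immediate early genes lower, with 1, 2 and 0 higher. None of 22 interferon-stimulated genes passed the edgeR quasi-likelihood test, also adjusted over the list alone (3 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom, 2 by the exact test), at a median of -0.15 and a camera adjusted p of 0.424. The integrated stress response had 0 of 15 by the same test, also adjusted over the list alone (4 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom, 1 by the exact test), at a median of -0.02 and a camera adjusted p of 0.696. Without vehicle library 1 the camera adjusted p of the interferon list was 0.00439, the number of NF-kB targets lower was 3 and that of immediate early genes lower was 1. Without vehicle library 3, 3 NF-kB targets and 6 immediate early genes were lower, and without any single CX library 0 genes of these 4 lists were called. Erythroid genes, at a median of -4.96, moved in the direction of the immediate early genes and NF-kB targets. With the erythroid level as a covariate the medians were 0.11 for immediate early genes, the opposite sign, -0.05 for NF-kB targets, 0.09 for interferon-stimulated genes and 0.20 for the integrated stress response, each with 0 called by the edgeR quasi-likelihood test.

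In total, 1027 of 12679 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 10 h in p53WT AML, 479 higher and 548 lower, and 3979 had an unadjusted p under 0.05. The CX and vehicle libraries did not overlap in 4940 genes (39.0%), where chance gives 10%, and all 1027 called genes were among them. DESeq2 called 2314, and the count was 1678 without vehicle library 1, 25 without CX library 1, 23 without CX library 2 and 23 without CX library 3. With the erythroid level as a covariate it was 23 (1479 at an unadjusted p under 0.05), of which 13 were p53 targets. That covariate differed between the arms, so that the lower count cannot be read as the loss of a treatment effect.

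The second comparison asked how p53null AML responded to 10 h of CX-5461. Rdm1, a gene of the RAD52 family, had the largest rise past the FDR at a mean of at least 5 CPM, a log2 fold change of 0.50 (FDR 0.0305) in the authors' deposited table. The next largest rises in the authors' deposited table included 3 genes of the G2/M list, Ube2c, Ccnb1 and Aurka. The ubiquitin-conjugating enzyme gene Ube2c had a log2 fold change of 0.47 (FDR 2.76e-07), the cyclin gene Ccnb1 0.41 (FDR 0.000172), the phosphatase gene Cdc25b 0.44 and the kinase gene Aurka 0.38 in the authors' deposited table. The importin gene Kpna2 rose by 0.37, the mitochondrial ribosomal RNA gene mt-Rnr2 by 0.35 and the histamine-forming enzyme gene Hdc by 0.34 in the authors' deposited table. Falls past the FDR at that mean level were those of the glucosamine-phosphate deaminase gene Gnpda2 (-0.47), the uracil glycosylase gene Ung (-0.43) and the phosphatase gene Dusp2 (-0.43), per the authors' deposited table. That of the p53 target Cdkn1a was -0.03 (FDR 1) and that of Bbc3 -0.28 (FDR 0.825) in the authors' deposited table, which does not hold Phlda3, Plk2 or Zmat3. A total of 24 of 12861 genes passed an FDR of 0.05 in the authors' deposited table, 19 higher and 5 lower, and 781 had an unadjusted p under 0.05.

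All 29 measured G2/M genes had a positive log2 fold change in the authors' deposited table for p53null AML, 8 rose and 0 fell, and 21 rose when adjusted over the list alone. Besides those above, Cdk1 (0.27), Kif20a (0.32), Prc1 (0.28), Hmmr (0.26) and Tpx2 (0.24) rose in the authors' deposited table. The G2/M median was 0.22, and the list rose by cameraPR on the authors' deposited table (adjusted p = 3.18e-45, and 1.24e-13 on ranks). That test preset the correlation between genes at 0.01, while 0.52 was estimated for this list in p53WT AML at 10 h. Of 28 G1/S genes in the authors' deposited table, 0 rose and 1 fell, Ung, with 4 lower when adjusted over the list alone, at a median of -0.04 (adjusted p = 0.000939 by cameraPR). The erythroid list, with 6 genes in the authors' deposited table, had a median of -0.12 and was not called (adjusted p = 0.256).

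None of 29 p53 targets passed in the authors' deposited table for p53null AML, with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone, at a median of -0.05 (cameraPR adjusted p = 0.152). Lists that moved by cameraPR with 0 genes past the FDR in the authors' deposited table were MLL fusion and stemness genes (median -0.11, adjusted p = 0.000131, 2 of 21 genes at an unadjusted p under 0.05), monocyte and macrophage genes (0.10, adjusted p = 0.000359, 4 of 22) and interferon-stimulated genes (0.14, adjusted p = 0.000359, 1 of 22). Ribosome biogenesis genes had a median of -0.03 in the authors' deposited table, with 0 of 40 past an unadjusted p of 0.05 and an adjusted p of 0.0508, or 0.0134 on ranks. Medians and cameraPR adjusted p from the authors' deposited table were 0.00 and 0.618 for 15 Pol I machinery genes, -0.01 and 0.333 for 77 ribosomal protein genes and -0.13 and 0.172 for 3 histones. They were 0.06 and 0.175 for 10 primary granule genes and -0.02 and 0.493 for 24 neutrophil genes in the authors' deposited table. For 19 BCL2 family genes they were -0.03 and 0.217, for 17 NF-kB targets 0.01 and 0.493, for 19 integrated stress response genes -0.07 and 0.156 and for 19 cholesterol synthesis genes -0.03 and 0.238, again from the authors' deposited table. Each of these 9 lists had 0 genes past the FDR in the authors' deposited table, and 1, 0, 1, 1, 1, 0, 2, 1 and 1 at an unadjusted p under 0.05 in the order given. DNA damage genes had a median of 0.02 (adjusted p 0.252) with Cdc25b higher, and immediate early genes a median of 0.01 with a mean of 0.11 and a test direction that was down (adjusted p 0.592, 0 genes past the FDR and 6 of 14 at an unadjusted p under 0.05), per the authors' deposited table. The authors' deposited table gave the remaining marrow cell lists medians of 0.10 for B cells (adjusted p 0.123), 0.06 for T and NK cells (0.264), -0.23 for megakaryocytes (0.164), -0.11 for stroma and endothelium (0.152) and -0.08 for mast cells, basophils and eosinophils (0.172). These 5 lists had 0 genes past the FDR in the authors' deposited table, with 1, 0, 0, 1 and 2 at an unadjusted p under 0.05.

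The third comparison asked what p53WT AML looked like after 72 h of CX-5461. At a mean of at least 5 CPM, the 8 largest rises past the FDR in the authors' deposited table were led by the basophil protease gene Prss34. It had a log2 fold change of 3.89, Cd5l 3.67, Siglec1 3.52, Mertk 3.42, Maf 3.41 and Axl 3.26, the ficolin gene Fcna 3.40 and the eosinophil receptor gene Ccr3 3.28 in the authors' deposited table. The 8 largest falls at that mean level in the authors' deposited table were those of Apba1 (-2.03), the integrin gene Itga1 (3.99-fold lower) and the interferon-induced genes Ifi209 (-1.92), Rtp4 (-1.82), Ifit1 (-1.76), Usp18 (-1.72), Oasl2 (-1.68) and Slfn5 (-1.61). A total of 4002 of 12838 genes passed an FDR of 0.05 in the authors' deposited table, 2064 higher and 1938 lower, of which 419 and 146 had an absolute log2 fold change of at least 1.

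Targets of p53 were still higher at 72 h: 20 of 32 measured rose and 0 fell in the authors' deposited table, with 23 higher and 1 lower when adjusted over the list alone. Their median log2 fold change was 0.45, and the list rose by cameraPR on the authors' deposited table (adjusted p = 1.69e-18). The authors' deposited table gave log2 fold changes of 3.08 for Phlda3, 2.57 for Plk2, 1.95 for Zmat3, 1.70 for Cdkn1a (FDR 1.44e-32), 1.53 for Sesn2, 0.59 for Mdm2 and 0.54 for Bbc3. Erythroid genes (median 1.48, the globins -0.10), 7 of 7 mast cell, basophil and eosinophil genes and 4 of 4 Y-linked genes moved in the same direction in the authors' deposited table.

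Neutrophil maturation genes rose at 72 h, 21 of 24 with 1 lower in the authors' deposited table (22 and 2 when adjusted over the list alone), at a median of 0.97 (cameraPR adjusted p = 5.21e-31). The neutrophil surface gene Ly6g (2.61), the lactoferrin gene Ltf (2.10) and the formyl peptide receptor gene Fpr2 (1.89) rose, and the haptoglobin gene Hp fell by 0.21 in the authors' deposited table. The list test preset the correlation between genes at 0.01, while 0.61 was estimated for neutrophil genes in p53WT AML at 10 h. All 7 mast cell, basophil and eosinophil genes rose in the authors' deposited table, at a mean log2 fold change of 2.05 (adjusted p = 9.6e-10), among them Cpa3 (3.10) and the eosinophil peroxidase gene Epx (2.83). Of 22 monocyte and macrophage genes in the authors' deposited table, 9 rose and 7 fell (10 and 8 when adjusted over the list alone), at a median of 0.06 and a mean of 0.56 (adjusted p = 0.113). The macrophage genes C1qc (3.01), C1qb (2.81) and Mrc1 (3.11) and the oxidase gene Cybb (1.13) rose there, and the monocyte factor gene Irf8 (-1.42), Ly86 (-1.38) and Ccr2 (-0.54) fell, per the authors' deposited table. Markers of other lineages rose with them in the authors' deposited table, with medians of 1.48 for erythroid genes (8 of 14 higher, 0 lower, adjusted p = 0.00756), 1.37 for megakaryocyte genes (3 of 5 higher, adjusted p = 0.00756) and 1.42 for B cell genes (3 of 5 higher, adjusted p = 0.0128, or 0.161 on ranks). Within the erythroid list, the 4 globin genes, at a median of 248 CPM, had a median log2 fold change of -0.10 with 0 past the FDR, and the other 10, at 5.17 CPM, had 1.78 in the authors' deposited table. T and NK cell genes (2 of 3 higher, median 1.02, adjusted p 0.0993) and stromal and endothelial genes (0 of 5 higher, 1 lower, median 0.11, adjusted p 0.88) were not called in the authors' deposited table. Y-linked genes, which neither 10 h table holds, also rose with them, 4 of 4 in the authors' deposited table.

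Some genes of immature myeloid and stem cells fell at 72 h. In the MLL fusion and stemness list, 8 of 22 fell and 1 rose, also when adjusted over the list alone, at a median of -0.10 (adjusted p = 0.00721) in the authors' deposited table. The transcription factor gene Sox4 (-1.11), the receptor gene Kit (-0.87), Myc (-0.77), Cd34 (-1.23) and Mecom (-1.54) fell and the receptor gene Flt3 (0.84) rose, while Hoxa9 had -0.06 (FDR 0.722) and Meis1 0.12 (FDR 0.376) in the authors' deposited table. Of 10 primary granule genes, 6 fell and 1 rose in the authors' deposited table (7 and 1 when adjusted over the list alone), at a median of -0.25 (adjusted p = 0.00721). The transcription factor gene Cebpa (-0.75) and the protease genes Prtn3 (-0.52) and Elane (-0.53) fell, as did the myeloperoxidase gene Mpo (-0.34), and Fcnb (0.95) rose in the authors' deposited table. Markers of other cells rose in the same authors' deposited table, erythroid genes at a median of 1.48 (the globins at -0.10), 7 of 7 mast cell, basophil and eosinophil genes and 4 of 4 Y-linked genes.

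Interferon-stimulated genes fell together at 72 h, 19 of 21 with 0 higher in the authors' deposited table, also when adjusted over the list alone, at a median of -0.92 (cameraPR adjusted p = 8.05e-30). Examples from the authors' deposited table were Irf7 (-1.52), which encodes a regulator of interferon genes, Xaf1 (-1.47) and Bst2 (-1.23), which encodes tetherin. The list test preset the correlation between genes at 0.01, while 0.785 was estimated for interferon-stimulated genes in p53WT AML at 10 h. The integrated stress response rose, 8 of 16 with 0 lower (median 0.41, adjusted p = 0.00744), with Atf4 at 0.61, Dnajb9 at 0.60 and Herpud1 at 0.49 in the authors' deposited table. Immediate early genes rose, 7 of 13 with 0 lower (median 0.58, adjusted p = 0.0123), with Dusp1 at 2.17, Zfp36 at 0.73 and Klf6 at 0.67 in the authors' deposited table. NF-kB targets rose, 6 of 16 with 0 lower (median 0.22, adjusted p = 0.0115), with Relb at 0.84, Icam1 at 0.74 and Nfkbia at 0.60 in the authors' deposited table. Neutrophil maturation genes, at a median of 0.97, and erythroid genes, at 1.48 (the globins at -0.10), moved with these 3 lists in the authors' deposited table, and against the interferon list. So did 7 of 7 mast cell, basophil and eosinophil genes and 4 of 4 Y-linked genes in the authors' deposited table.

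Ribosomal protein genes fell slightly at 72 h, 12 of 77 with 1 higher (5 and 0 when adjusted over the list alone), at a median of -0.12 (adjusted p = 0.00721), with Rpl39 at -0.37 and Rpl13a at -0.31 in the authors' deposited table. DNA damage genes fell, 5 of 28 with 0 higher (median -0.13, adjusted p = 0.0257), with the histone variant gene H2afx at -0.67 and Timeless at -0.36 in the authors' deposited table. Against both falls, 8 of 14 erythroid genes (median 1.48, the globins -0.10), 7 of 7 mast cell, basophil and eosinophil genes and 4 of 4 Y-linked genes were higher in the authors' deposited table. The other lists were not called in the authors' deposited table. Pol I machinery had 2 higher and 1 lower of 15 (median -0.02, adjusted p 0.837) and ribosome biogenesis 3 higher and 4 lower of 40 (0.02, 0.984), where the test direction was opposite in sign to the median for both, per the authors' deposited table. Cholesterol synthesis had 1 higher and 4 lower of 19 (-0.07, 0.374), with Sqle at -0.39, in the authors' deposited table. Cell cycle genes in the authors' deposited table were 2 higher and 5 lower of 28 for G1/S (-0.07, 0.222), with Ccne1 at 0.57 and Ung at -0.51, and 0 higher and 1 lower of 29 for G2/M (-0.05, 0.554). BCL2 family genes were 6 higher and 3 lower of 18 (0.08, 0.222), with Mcl1 at 0.64, and histones 1 higher and 0 lower of 3 (0.45, 0.561) in the authors' deposited table.

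**Figure D3:**
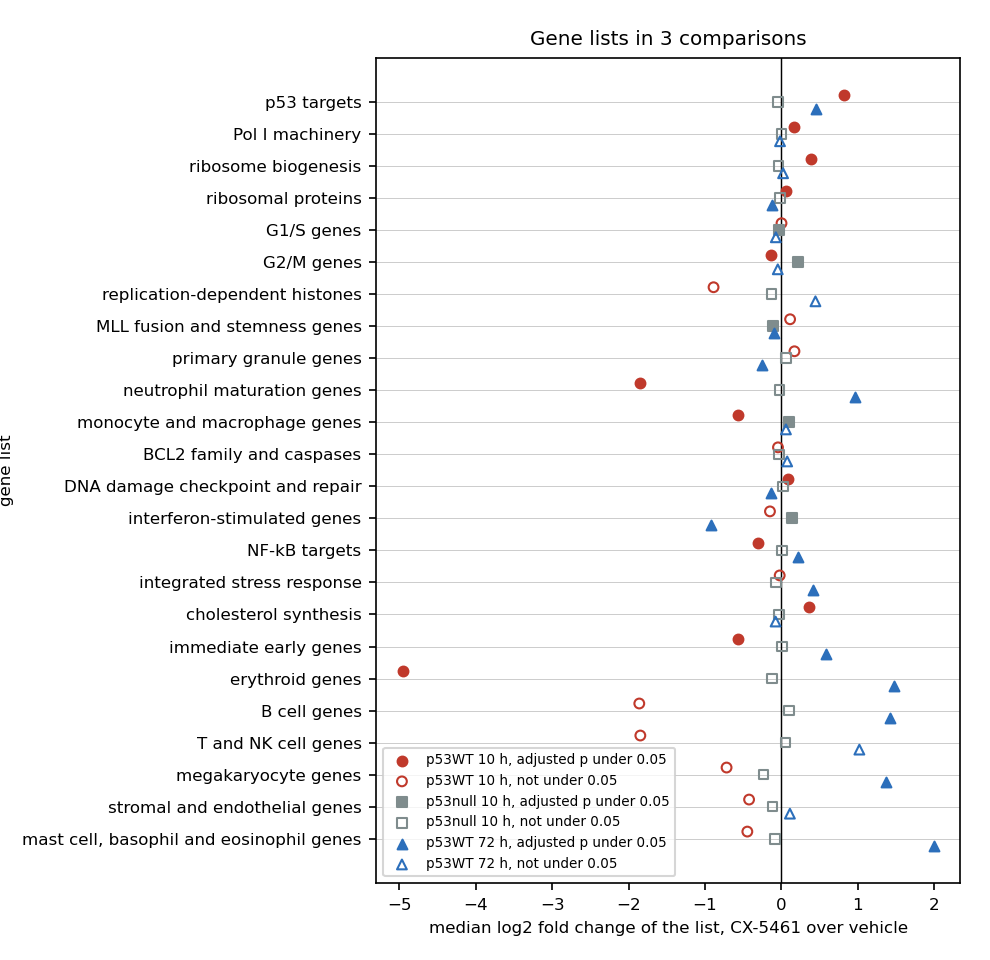
Median log2 fold change (horizontal axis) of each of the 24 gene lists (vertical axis) with CX-5461 over vehicle in p53WT AML at 10 h (circles, from counts), p53null AML at 10 h (squares) and p53WT AML at 72 h (triangles), the last 2 from the authors' deposited tables, with filled symbols for an adjusted p under 0.05. Neutrophil maturation genes had medians of -1.85, -0.02 and 0.97 in the 3 comparisons, the last 2 from the authors' deposited tables.

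Across genotypes at 10 h, p53 target genes differed in their response. Over the 29 members in both tables, the log2 fold change in the authors' deposited tables was larger in p53WT than in p53null AML by a median of 0.70, and 24 of the 29 differences were positive (adjusted p = 1.15e-06 by cameraPR on the ranked differences). No called gene was shared by the 2 comparisons in any direction over 11879 genes measured in both, where independent lists would share 0.713 higher genes and 0.175 lower genes (the p53null calls are from the authors' deposited table, with 24 genes). G2/M genes differed the other way, by a median of -0.37 with 0 of 29 positive (adjusted p = 5.39e-08), and ribosome biogenesis genes by 0.42 with 40 of 40 positive (adjusted p = 9.91e-13), from the authors' deposited tables. Erythroid genes differed by -4.63 and neutrophil genes by -1.71 between the same authors' deposited tables. Genotype was confounded with the table and with the tag in the sample titles, and differences of single genes were not tested.

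In p53WT AML, p53 targets were higher at both 10 and 72 h. Of 32 list members in both tables, 21 were higher at 10 h, 20 at 72 h in the authors' deposited table and 18 at both, and 17 of those 18 had the larger log2 fold change at 10 h. The median difference, 72 h minus 10 h, was -0.38 in the authors' deposited tables (adjusted p = 0.00505 by cameraPR on ranked differences, and 0.0614 without ranks). Of 542 genes called lower at 10 h, 262 (48.3%) were higher in the authors' deposited table at 72 h, where independent lists would share 84.2 (Fisher's exact test, adjusted p = 5.64e-75). Without CX library 1, 2 or 3, only 1, 0 and 0 genes were called lower at 10 h, and 0 with the erythroid covariate. Fisher's exact test treats genes as independent, while estimated correlations at 10 h were 0.61 for neutrophil and 0.97 for erythroid genes. Its p-values do not measure a spread between animals. Genes higher at 10 h were higher at 72 h in the authors' deposited table in 85 cases against 73.0 for independent lists (Fisher's exact test, adjusted p = 0.287). This depended on the calls used. With an absolute log2 fold change of at least 1 at both times it was 14 against 0.871 (unadjusted p = 4.4e-14), from the edgeR quasi-likelihood test at 10 h and the authors' deposited table at 72 h. With the authors' deposited table at both times it was 92 against 66.9 (unadjusted p = 0.00112). DESeq2 at 10 h gave 153 against 149 with the authors' deposited table at 72 h (unadjusted p = 0.71). Lower at both times were 50 genes against 84.4 (Fisher's exact test, adjusted p = 7.15e-05), with the 72 h calls from the authors' deposited table. Neutrophil genes differed by 2.97 (adjusted p = 1.24e-10), erythroid genes by 5.75 (adjusted p = 1.6e-07), immediate early genes by 1.29 (adjusted p = 0.000344) and interferon-stimulated genes by -0.82 (adjusted p = 6.42e-05) in the authors' deposited tables. Across 12277 genes the log2 fold changes of the authors' deposited tables correlated at r = -0.34 between the times (Spearman rho -0.16), and across the 32 p53 targets at r = 0.87, where genes are not independent replicates.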

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

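The 10 h tests of p53WT AML were planned, while the tests of list differences, of splits and of candidate sources in this part were chosen after the results were seen. List differences between p53WT and p53null AML at 10 h, as the median difference of log2 fold changes in the authors' deposited tables, passed for 15 lists by cameraPR on ranked differences. The response was higher in p53WT AML for p53 targets (0.70, 24 of 29 members), Pol I machinery (0.21), ribosome biogenesis (0.42, 40 of 40), ribosomal proteins (0.0744), MLL fusion and stemness genes (0.21) and cholesterol synthesis (0.38). It was lower for G2/M genes (-0.37), replication-dependent histones (-0.87), neutrophil maturation genes (-1.71), monocyte and macrophage genes (-0.72), interferon-stimulated genes (-0.29), NF-kB targets (-0.33), immediate early genes (-0.56), erythroid genes (-4.63) and mast cell, basophil and eosinophil genes (-0.37). Without ranks, the adjusted p was 0.065 for Pol I machinery, 0.065 for ribosomal proteins, 0.0524 for histones and 0.215 for MLL fusion and stemness genes.

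Between 72 h and 10 h of CX-5461 in p53WT AML, the same test on the authors' deposited tables separated 18 lists. The response was higher at 72 h for G2/M genes (0.11), neutrophil maturation genes (2.97), monocyte and macrophage genes (0.45), NF-kB targets (0.53), the integrated stress response (0.43), immediate early genes (1.29), erythroid genes (5.75), B cell genes (1.64), megakaryocyte genes (1.64) and mast cell, basophil and eosinophil genes (1.51). It was lower at 72 h for p53 targets (-0.38), ribosome biogenesis (-0.35), ribosomal proteins (-0.18), MLL fusion and stemness genes (-0.18), primary granule genes (-0.51), DNA damage genes (-0.27), interferon-stimulated genes (-0.82) and cholesterol synthesis (-0.36). Without ranks, the adjusted p was 0.0614 for p53 targets, 0.0581 for ribosomal proteins, 0.785 for G2/M genes, 0.154 for MLL fusion and stemness genes, 0.254 for primary granule genes and 0.136 for DNA damage genes. Differences between time points were confounded with the table and with the tags in the sample titles, as were those between genotypes. Groups of 3 are too small for a test of single deviating samples.

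The real split of the 6 libraries of p53WT AML at 10 h gave 1027 genes, the highest of the other splits gave 0, and 1 of 10 splits gave as many as the real one. With 10 splits, a share under 0.05 cannot be reached.

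The first pattern was the rise of p53 targets at 10 h in p53WT AML. A higher share of leukemia cells in the CX libraries would raise MLL fusion and stemness genes as much, but the p53 median exceeded theirs by 0.70, where the SE of their mean was 0.123. With the erythroid level as a covariate, 12 of the 22 called p53 targets still passed, while the list median was 0.91 against 0.82 without it and the median SE 0.135 against 0.0960. Relative to the CX mean, the erythroid median was 4.09, 5.88 and 1.15 in vehicle libraries and -0.15, -0.12 and 0.08 in CX libraries. The covariate was thus confounded with treatment, and calls kept or lost with it do not decide the question. A response that needs p53 is a candidate explanation, since the median difference to p53null AML was 0.70 (adjusted p = 1.15e-06). Genotype was confounded with the table and with the tag in the sample titles. A difference between the tables or between the leukemias behind them therefore stays open.

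The second pattern was the joint fall of neutrophil and erythroid genes at 10 h in p53WT AML. Other marrow cells in the vehicle libraries are a candidate source: the erythroid median was -4.96, and Hbb-bs, a globin gene among the most abundant of that cell type, reached 1606, 5935 and 169 CPM in the vehicle libraries against 71.4, 135 and 104 CPM. The GFP sort would remove such cells, and the CX libraries expressed 4 of 12 erythroid genes and 21 of 24 neutrophil genes at 5 CPM or more. Lower maturation of the leukemia cells could not be told apart from it for the neutrophil genes, whose median with the erythroid level as a covariate was -0.39, with 0 called by the edgeR quasi-likelihood test and 20 of 24 below 0. No measured gene marks GFP-negative cells, so both stay open.

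The third pattern was the rise of mature blood cell genes at 72 h in p53WT AML, from the authors' deposited table. A lower share of leukemia cells, with all other marrow cells raised alike, would raise the globins too. Their median was -0.10 (-0.23 to -0.09), while the other 10 erythroid genes had 1.78 in the authors' deposited table. The vehicle excess at 10 h had a ratio of globin to other erythroid CPM of 9.83. With that ratio, the rise of the 8 other genes in both tables would have brought a globin log2 fold change of 0.96 at 72 h. This argues against that source only if the ratio held at 72 h, which could not be checked. Globins together stood at 963 CPM in vehicle at 72 h, so that a smaller addition could go unseen. Cells of recipient origin in the CX libraries are a candidate source for part of it, since 4 of 4 Y-linked genes were higher in the authors' deposited table while Xist fell by 0.44, but the sex of donors and recipients is not given and the GFP sort would remove such cells. Maturation of the leukemia cells could not be told apart from this, with a primary granule median of -0.25 and 22 of 24 neutrophil genes and 5 of 7 mast cell, basophil and eosinophil genes at 5 CPM or more in the authors' deposited table, which holds no value per library.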

How the results depend on the processing

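The alternatives that added a covariate or a block, robust estimation, an FDR of 0.01, rank forms and tests without ranks were chosen after the data were seen, and the others were planned. The 1027 genes of p53WT AML at 10 h (479 higher, 548 lower) stayed within 1.5 times with RLE size factors, library size alone (432 higher and 462 lower), robust estimation and other filters, which removed no gene. DESeq2 gave 2314 (962 higher, 1352 lower), and lower genes were 919 by the exact test, 330 by limma-voom and 866 in the authors' deposited table. The erythroid covariate gave 23 (23 higher, 0 lower by the edgeR quasi-likelihood test), and an absolute log2 fold change of at least 1 gave 194 (46 higher, 148 lower). Leaving out 1 library gave 23 to 1678 genes, 23 to 817 higher and 0 to 861 lower, the lowest without CX libraries 2 and 3 and the highest without vehicle library 1. The cause was not tested. An absolute log2 fold change of at least 1 left 0 genes in p53null AML (0 higher, 0 lower of 24) and 565 in p53WT AML at 72 h (419 higher, 146 lower) of the authors' deposited tables, by construction. The overlap of genes higher at both times was 14 with that threshold and 153 by DESeq2, and that of genes lower at 10 h and higher at 72 h was 468 in the authors' deposited table, 73 with the threshold and 562 by DESeq2.

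Of 89 named genes of p53WT AML at 10 h, none was called in the opposite direction under the alternatives run. Signs did change with the erythroid covariate. All 3 B cell and all 3 histone genes named were negative without it, and with it 0 of either list were below 0. All 89 kept their side of the threshold with RLE size factors, while 36 were no longer past it with the covariate, 15 by limma-voom, 9 with robust estimation and 37, 38 and 38 without CX library 1, 2 or 3, and DESeq2 added 25. Of 24 lists at 10 h, none of the 12 called by camera passed with an estimated correlation, and fry lost 8 and added 1. No correlation could be estimated for the cameraPR tests of the other 2 tables or of list differences, which used no values per library. On ranks, 1 list was added in p53null AML and 1 lost at 72 h, and without ranks 10 list differences were lost and 3 added. The number in the count column names was used as a replicate block, although no source ties equal numbers to each other. Deviations from the group means correlated across genes at r = 0.301, 0.106 and 0.0274 between columns of the same number, and CX library 3 correlated best with vehicle library 2, at 0.0933. This replicate block gave 1536 genes, 679 higher and 857 lower, with 9 named genes and 1 list (mast cell, basophil and eosinophil genes, adjusted p = 0.0493) added and none lost. No paired analysis was possible because of missing counts in the other 2 tables, nor with the title numbers, which the count columns do not give. Planned but not run without those counts were fits of p53null AML and of p53WT AML at 72 h with their alternatives, the genotype and time interactions and the contrast of the vehicle groups. The p53WT fit at 10 h recovered 44% of simulated genes at an absolute log2 fold change of 0.5. Changes of that size were therefore often missed in the simulated counts at this depth and n = 3. They may be missed in the real counts too. The simulation gave both arms the same dispersion, while the real vehicle libraries differed more among themselves than the CX libraries. Its recovery shares therefore need not hold for the real counts.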

Other observations

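Genes called whichever single CX library was left out numbered 22 in p53WT AML at 10 h, all higher, with 13 in the p53 list. The other 9 were picked out after their values were seen. Inka2, an inhibitor of the kinase PAK4, rose from 0.494 ± 0.158 to 8.97 ± 0.289 CPM (log2 fold change 4.12, SE 0.210), and Gtse1, a microtubule-associated regulator of p53, from 61.7 ± 3.25 to 144 ± 3.01 CPM (1.22, SE 0.0536). The apoptosis suppressor gene Ddias (1.22), the actin regulator gene Kank3 (1.39), the lipase inhibitor gene Angptl4 (0.88), Slc19a2 (1.83), Qpctl (0.71), Exoc4 (0.70) and D630023F18Rik (1.40) were the others. At 72 h, 7 of these 9 rose in the authors' deposited table, among them Inka2 (2.78), Slc19a2 (0.65), Qpctl (0.55) and Gtse1 (0.44), while Angptl4 had 0.03 and Kank3 0.12. In p53null AML, 7 of the 9 were in the authors' deposited table, 0 past the FDR and 1 at an unadjusted p under 0.05 (Gtse1, 0.16).

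The immunoglobulin genes Ighg2c and Igkc were looked at after their values were seen, and the B cell list was not called in p53WT AML at 10 h (camera adjusted p 0.195). Ighg2c stood at 79.6, 64.9 and 15.0 CPM in vehicle libraries 1, 2 and 3 and at 0.975, 0.367 and 0.681 CPM in the CX libraries, and Igkc at 99.1, 173 and 15.7 against 18.2, 10.6 and 15.5 CPM, with an adjusted p of 0.0660 for Igkc in the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment. Xist, the RNA that silences an X chromosome, had 824 ± 250 CPM in vehicle and 1241 ± 133 CPM with CX-5461, with an adjusted p of 0.126 in the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment. The Y-linked genes Ddx3y (2.19), Eif2s3y (2.30), Kdm5d (3.16) and Uty (1.89) rose at 72 h in the authors' deposited table, where Ddx3y had a mean of 2.25 CPM and Xist 951 CPM.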
